A study of Mus musculus with 4 samples.

How the data were processed

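Gene expression was measured on Affymetrix MOE430A_2.0 arrays in CD4 and CD8 T cells sorted from the spleens of Gfi1 knockout and wildtype mice. Each of the 4 groups has 1 array, and RNA of 2 mice was pooled for each, per the labels. RNA was extracted with TRIzol and labelled with biotin, per the labels' protocols. The submitters' processing notes name GCOS 1.4 and MAS5, and further steps are not given in the sources used here. The deposited values are linear signal intensities per probe set. From the values themselves, each array has a 2% trimmed mean near 1000, so the authors' values appear scaled to a common level, which assumes that most RNA is at one level on all arrays. Detection calls were not used here. Of 22690 probe sets, 64 are controls and were left out.

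Probe sets were named through the platform annotation supplied with the series. A single gene symbol was listed for 20380 probe sets, several for 691, and 1555 non-control probe sets were not listed and stay unnamed; those with several symbols were not used for genes. Of the probe sets with 1 symbol, 20351 matched a gene of the mouse RefSeq annotation (GRCm38.p6), which was used for current names and for neighbours of Gfi1 only, since no genome build is named for the array; no coordinates are given. Each gene was represented by the probe set with the highest mean log2 value, which gave 12393 genes.

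Signals below a floor, the 40th percentile of all non-control values (93.9), were set to it before taking log2, and a fold with an array at the floor is a lower bound. No fold is given where both arrays are at the floor. Differences are log2 of the array labelled knockout minus the array labelled wildtype, or of CD8 minus CD4. With 1 array per group, differences within a subset have no p-value; counts of genes at least 2-fold apart are given, with the count that independent lists would share. The only model with a residual degree of freedom was limma 3.58.1 (R 4.3.3; lmFit and eBayes with trend, prior degrees of freedom 5.11) with subset and genotype as terms, on 8596 genes above the floor on at least 1 array, with Benjamini-Hochberg adjustment and a threshold of 0.05. Limma's error here joins the difference between the subsets, over 1 degree of freedom, with a prior spread taken from genes of like expression. With 5.11 prior degrees of freedom, most of its weight lies on that prior. Neither part measures a spread between animals, so adjusted p-values describe these arrays only. The other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

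There were 29 gene lists, fixed with the comparisons and the alternatives before the data were examined. For each, the median log2 fold was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays. Members at the floor enter a median at their bound. Members count as higher or lower in both subsets at 1.5-fold. The genes named in the text follow a rule fixed at the same time: Gfi1; the 10 genes each way with the largest smaller fold over both subsets, and up to 5 each way with an array at the floor; the 5 each way with the largest fold in each subset and in the difference between the subsets, above the floor on the arrays compared; the 10 each way of CD8 against CD4 with the members of the lists for these subsets; up to 4 members of each list; and always Il7r and Cd44. Other genes were chosen after their values were seen: further calls of limma (such as Clec2d, Klrc1, Bub1b and Ctsw), further members of the lists (such as Prf1, Il18r1, Flt3 and Blk), Irf8, and the genes of opposite direction in the subsets. Of 158 named genes, 56 had another probe set above the floor, and for 14 another probe set gave an opposite sign in a subset. For 3 of these (Ahr, Ifngr2 and Il10ra) the fold used was at least 2.

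Ratios of 3' to 5' signal were between 1.13 and 1.21 for Actb and between 0.80 and 0.88 for Gapdh, and 58.4% to 61.6% of probe sets lay above the floor. Other controls were uneven: lys differed between the labelled genotypes by a log2 value of -0.74 in CD4 and -0.69 in CD8 cells, and the 18S ribosomal RNA control was also lower on the arrays labelled knockout, at 3562 in CD4 and 525 in CD8 cells against 7147 and 7228 on those labelled wildtype. Over 12162 probe sets above the floor on all arrays, Pearson correlations between arrays ran from 0.944 to 0.974. The limma step was tested on simulated data for the genotype effect on 8596 genes: of 40 genes for each size, 22.5% were called at a log2 change of 1 and 15.0% at -1, 90.0% at 2 and 87.5% at -2, and 97.5% at 3, with 3 calls among 8396 unchanged genes. The simulated noise was normal, with a shared spread for genes of like expression, and without the floor. It held no gene with an unusually large difference between the subsets' effects, which limma takes as error. These rates therefore describe the simulation and not the arrays, where Cxcr3 was not called at a fitted log2 fold of -4.20. Of 100 random lists of 20 genes, 4 lay in the outer 5% without a shift in the CD4 comparison, and 100 lay above it when shifted by 1 log2 unit.

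The alternatives were quantile normalization, centring of arrays on their medians, a floor at the 25th (35.6) or 60th percentile (449.9), no floor, the mean of all probe sets of a gene, leaving out probe sets that may detect several transcripts, log2 of the value plus 16, thresholds of 1.5-fold and 3-fold, eBayes without trend, and leaving out each array. Restriction to genes above the floor on all 4 arrays was added after the data were seen. The tests of explanations in the closing section have their own criteria; that for genes near Gfi1 was written before its result was seen and the others afterwards.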

Results

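CD4 and CD8 T cells labelled as coming from Gfi1 knockout mice were set beside those labelled wildtype by expression array, with naive cells as the stated aim. Gfi1 encodes a zinc finger repressor of transcription in blood cells. Spleen cells of C57BL/6 mice had been stained for CD4, CD8 and CD44 and sorted by flow cytometry. CD44 is an adhesion receptor that naive T cells carry at a low level and antigen-experienced T cells at a high level, and every sample is described as CD44 low. There were 4 groups, the knockout and the wildtype genotype in each subset, with 1 array per group and the RNA of 2 mice pooled on each array. No group had a replicate, so no spread between animals could be measured, and the number of arrays limits the precision of every value. The values are signal intensities of 22690 probe sets. They covered 12393 named genes, of which 8596 lay above the floor of 93.9 on at least 1 array and 6882 on all 4. Median signals were 189 for the array labelled knockout CD4, 193 for knockout CD8, 235 for wildtype CD4 and 224 for wildtype CD8.

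Gfi1 signal was not lower in the arrays labelled knockout. Its only named probe set read 2891 in the array labelled knockout CD4 against 2272 in the array labelled wildtype CD4, a log2 fold of 0.35. In CD8 cells it read 2447 against 1158, a log2 fold of 1.08. The limma fit did not call Gfi1 (adjusted p = 0.201), and the place of the probe set relative to the deleted part of the gene is not given in the sources used here, so the signal does not check the genotype labels if it lies outside that part. The subset labels matched their markers: Cd4 signal was 5470 and 5901 on the CD4 arrays and below the floor on both CD8 arrays, and Cd8a was 16639 and 15920 on the CD8 arrays and below the floor on both CD4 arrays. Cd44 went against a label. It read 8136 and 5740 on the arrays labelled wildtype CD4 and CD8, and 196 and 252 on the arrays labelled knockout CD4 and CD8, although all 4 samples are described as CD44 low. Genotype is therefore given as labelled, and each direction between the labelled genotypes goes along with this difference in Cd44.

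**Figure D1:**
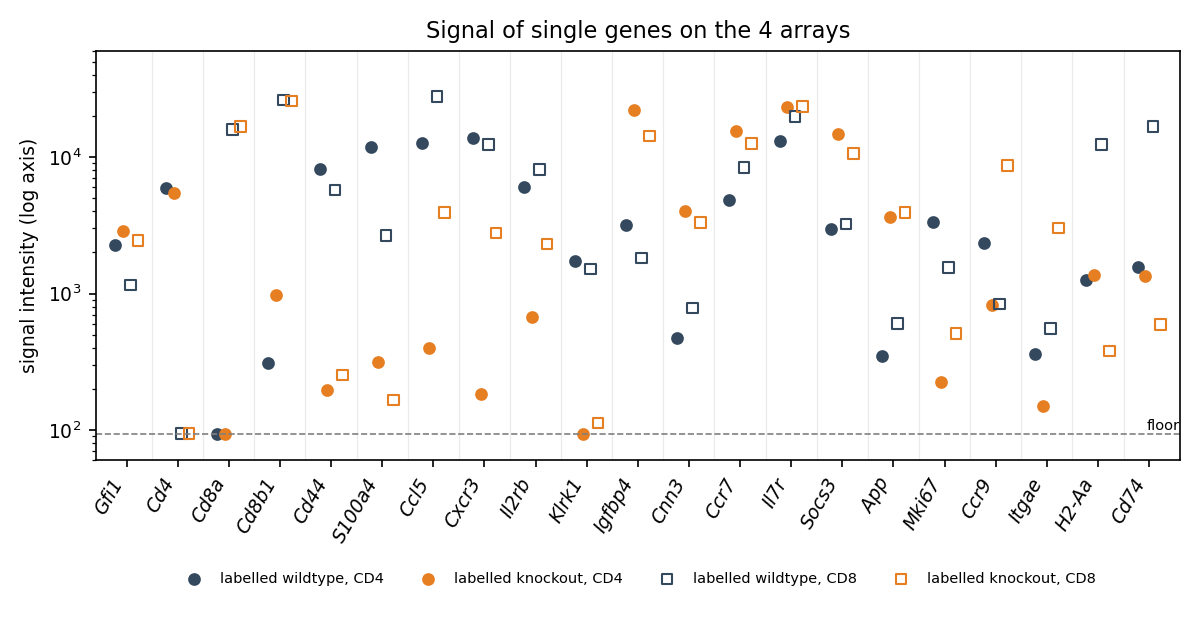
Signal intensity of single genes (log axis) on the 4 arrays, 1 point per array, with circles for CD4 and squares for CD8 cells, dark for the wildtype label and orange for the knockout label; values under the floor (dashed line, 93.9) are drawn at it. Cd44 reads 8136 and 5740 on the arrays labelled wildtype and 196 and 252 on those labelled knockout, while Gfi1 reads 2272 and 1158 against 2891 and 2447.

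In CD4 cells, the array labelled knockout had far less RNA of genes that memory and effector T cells express. Cxcr3, a chemokine receptor of type 1 helper and memory cells, was 75.5-fold lower, Cd44 41.5-fold, the calcium-binding protein gene S100a4 37.6-fold, the chemokine gene Ccl5 31.5-fold and S100a6 27.2-fold. Cxcr6, another chemokine receptor gene, read 12476 in the array labelled wildtype and lay below the floor in the array labelled knockout, at least 133-fold lower. The genes that were higher in the array labelled knockout included Myo6, which encodes an unconventional myosin (16.6-fold), Pdlim4 (12.8-fold), the amyloid precursor protein gene App (10.4-fold), Cnn3, which encodes a calponin (8.62-fold), and Igfbp4, which encodes a binding protein of insulin-like growth factors (6.89-fold). In all, 168 genes were at least 2-fold higher and 627 at least 2-fold lower in the array labelled knockout. The comparison has 1 array on each side and no test. The share of higher genes among these was 21.1% as deposited, 33.5% after quantile normalization and 47.3% with arrays centred on their medians, so the excess of lower genes depends on the scaling.

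In CD8 cells, Cd44, Ccl5, S100a6 and S100a4 were also lower in the array labelled knockout, and genes of antigen presentation stood out beside them. Cxcr6 was near level, at 3917 against 4323. Cd44 was 22.7-fold lower, Ccl5 7.13-fold and S100a6 6.60-fold, and S100a4 had a log2 fold of -4.00. The MHC class II genes H2-Eb1, H2-Aa and H2-Ab1 were 46.9-fold, 32.4-fold and 28.9-fold lower, and Cd74, whose product is the invariant chain of MHC class II, was 28.2-fold lower. Plek, which encodes a protein kinase C substrate of platelets and leukocytes, was 27.4-fold lower. Ccr9, the receptor for the gut and thymus chemokine CCL25, was 10.4-fold higher in the array labelled knockout, Igfbp4 7.79-fold, the cytochrome gene Cyp2s1 5.89-fold and Itgae, which encodes the CD103 integrin chain, 5.47-fold, and App had a log2 fold of 2.70. Across all genes, 98 were at least 2-fold higher and 343 at least 2-fold lower, with no replicate and no test. The share of higher genes was 22.2% as deposited, 33.6% after quantile normalization and 40.3% with arrays centred on their medians.

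The high MHC class II signal belonged to the array labelled wildtype CD8. Cd74 read 16735 there, against 1576 on the array labelled wildtype CD4, 1354 on knockout CD4 and 593 on knockout CD8. All 4 of these genes were at least 2-fold above each of the other 3 arrays. Of 9 dendritic cell genes that could be named, 4 were as well: Itgax (1003), Batf3 (312), Flt3 (287) and Xcr1 (250). Of 11 B cell genes outside MHC class II, Blk (200) was; Cd79b, Cd22 and Ighm were not, and the other 7 lay below the floor on all 4 arrays. The B cell gene Cd79a read 69.2 there and between 4.6 and 6.0 on the other arrays, all below the floor. Over all 12393 genes, 110 (0.89%) stood out on this array in the same way.

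Most of what differed strongly in both subsets differed in the same direction. There were 30 genes at least 2-fold higher and 178 at least 2-fold lower in the array labelled knockout in both subsets. Independent lists of these lengths drawn from all 12393 genes would share 1.3 and 17.4. Genes at the floor on all 4 arrays are among the 12393 and cannot differ, so these expected counts are low. Among the 6882 genes above the floor on all 4 arrays, 20 and 86 were shared, against 1.3 and 8.2 expected. Opposite directions were found for 9 genes, of which 8 were lower in CD4 and higher in CD8 (5.0 expected) and 1 the reverse (4.6 expected). Among genes above the floor on all 4 arrays these counts were 7 (3.5 expected) and 0 (3.1 expected). The 9 became 67 with a floor at the 25th percentile, 2 at the 60th, 198 with log2 of the value plus 16 and 615 without a floor. Without a floor, 225 genes were higher and 779 lower in both subsets. Ranked by the smaller of the folds among genes above the floor on all 4 arrays, Igfbp4 led the genes that were higher (log2 2.78 in CD4 and 2.96 in CD8), followed by App (3.37 and 2.70), Cnn3 (3.11 and 2.08), Cyp2s1 (1.93 and 2.56) and Socs3, a feedback inhibitor of cytokine signalling (2.31 and 1.71). For App the mean over the subsets was 3.04. Averaged probe sets lowered it to 1.401, and without multi-transcript probe sets it was 0, with the probe set left at the floor. Another multi-transcript probe set of App gave 2.651 in CD4 and 2.485 in CD8 cells. In the same ranking Cd44 led the genes that were lower (-5.37 and -4.51), followed by S100a4 (-5.23 and -4.00), the galectin gene Lgals3 (-3.80 and -3.89), the cysteine protease inhibitor gene Ctla2a (-3.44 and -3.29) and Ccl5 (-4.98 and -2.83). Outside this ranking, with an array at the floor, Pdlim4 was at least 12.8-fold higher in both subsets, Klrk1 was at least 13.4-fold lower in both, and Ccr2 had log2 folds of -3.98 and -3.46 or lower. Over the 6882 genes above the floor on all 4 arrays, the log2 folds of the subsets had a Pearson correlation of 0.458 and a Spearman correlation of 0.346, and 60.8% had the same sign; genes are not independent replicates. With arrays centred on their medians, the median fold of these genes lay at 0.33 in CD4 and 0.21 in CD8 cells, against 0.01 in CD4 as deposited. Among the shared genes, 30 against 178 were higher as deposited, 49 against 147 after quantile normalization and 65 against 130 with median centring.

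**Figure D2:**
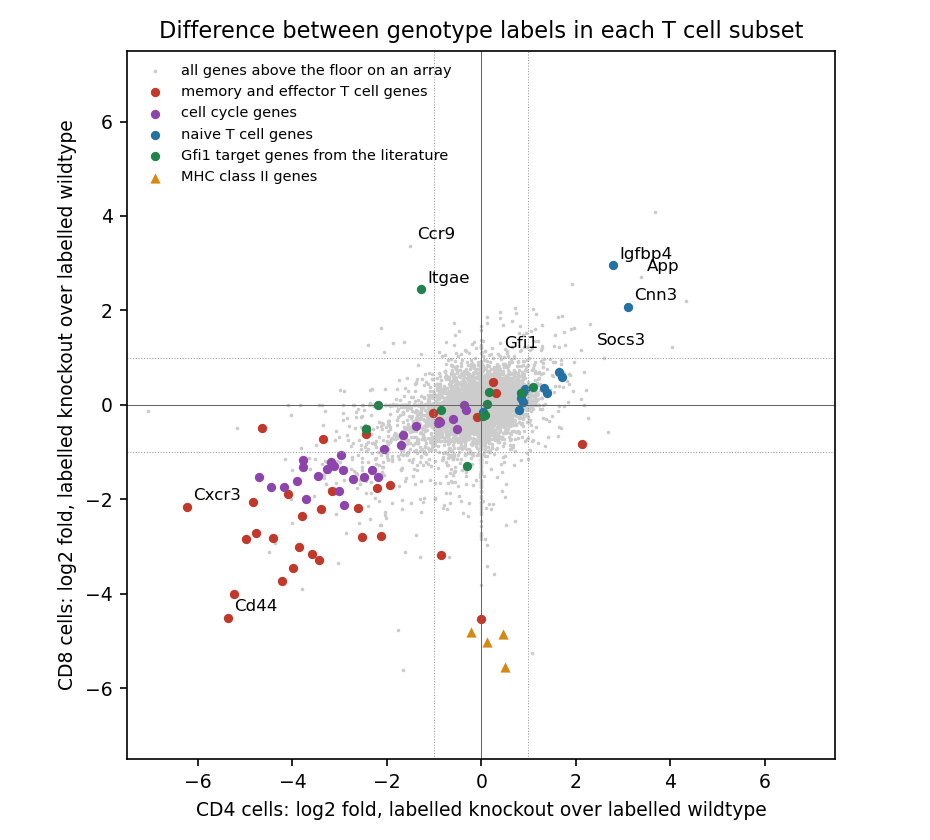
Each point is a gene, with its log2 fold (array labelled knockout over array labelled wildtype) in CD4 cells on the horizontal axis and in CD8 cells on the vertical axis; colours mark lists fixed beforehand and dotted lines mark 2-fold. Memory and effector genes (red) extend to the lower left, where Cd44 lies at -5.37 and -4.51, and MHC class II genes (triangles) are low in CD8 cells alone, with H2-Eb1 at -5.55 there.

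With the subset as a covariate, limma called 47 of 8596 genes at an adjusted p under 0.05, of which 7 rose and 40 fell in the arrays labelled knockout. The 7 were Igfbp4 (log2 2.87 ± 0.13 SE, adjusted p = 0.00198), Pdlim4 (adjusted p = 0.00689), App (0.00886), Socs3 (0.0138), Cnn3 (0.025), Clec2d, which encodes a C-type lectin (0.0294), and Ppic, a cyclophilin gene (0.0389). Among those that fell were Ctla2a (log2 -3.36 ± 0.15 SE, adjusted p = 0.00198), Cd44 (-4.94 ± 0.24 SE, adjusted p = 0.00229), the killer receptor genes Klrk1 (0.0114), Klrc1 (0.0191) and Klrg1 (0.0294), the granzyme gene Gzmk (0.0146), the chemokine receptor genes Ccr2 (0.0138) and Cxcr5 (0.0294), and Myb, a transcription factor gene (0.0114). Pdlim4, Klrk1, Klrc1, Klrg1, Gzmk and Ccr2 had at least 1 array at the floor, so no fitted fold is given for them. Each fell or rose on 2 of 2 pairs of arrays, which is no separate support, since the fit counts disagreement between the subsets as error. The fit has 1 residual degree of freedom and takes the difference between the subsets, moderated by the spread of genes of like expression, as its error. The SE of a gene therefore rests largely on other genes. It also treats the CD4 and CD8 arrays as independent, although the labels do not say that they came from different mice. The number of calls depended on the settings: limma called 0 without the trend (990 at an unadjusted p under 0.05, against 1123), 0 with averaged probe sets (747), 4 after quantile normalization and 17 with median centring, all among the 47, and 201 to 505 with a lower or no floor, with a pseudocount or among genes above the floor on all 4 arrays.

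Of the lists fixed before the data were examined, the memory and effector genes had the lowest median in CD4 cells and, after the B cell list with its MHC class II genes, the lowest in CD8 cells. Their median log2 fold was -3.37 in CD4 and -2.18 in CD8 cells, and 0 of 10000 random lists of matched expression had a median as low in either subset. Of 33 members above the floor, 24 were at least 1.5-fold lower in both subsets and 0 were higher in both. Limma called 16 as lower over all genes and 29 adjusted over the list alone, 28 of them lower. Besides Cd44, S100a4 and Ccl5 they include Il2rb, a shared chain of the IL-2 and IL-15 receptors (8.98-fold lower in CD4 and 3.53-fold in CD8; adjusted p = 0.0358), the interferon gamma gene Ifng (at least 21.2-fold and 7.05-fold lower; adjusted p = 0.0366), and Eomes, a T-box factor of memory cells (3.84-fold and 3.25-fold lower; adjusted p = 0.0294). Against the list, Il18r1 was near level (0.25 and 0.47), and the perforin gene Prf1 was higher in CD4 (2.13) and lower in CD8 cells (-0.84) in the array labelled knockout. Counts adjusted over a list alone, here and below, were made only as deposited and with the trend. In that fit 1123 of all 8596 genes had an unadjusted p under 0.05. Without the trend limma called 0 over all genes.

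Naive T cell genes were higher in the arrays labelled knockout. Their median was 0.92 in CD4 cells, above 10000 of 10000 random lists, and 0.26 in CD8 cells, above 9999. Of 13 members 3 were at least 1.5-fold higher in both subsets and 0 lower, 2 rose by limma over all genes (Igfbp4 and Cnn3), and 9 were called adjusted over the list alone. Ccr7, the receptor that guides T cells into lymph nodes, had log2 folds of 1.70 in CD4 and 0.58 in CD8 cells (adjusted p = 0.136). Bach2, a repressor of effector genes, was 3.11-fold and 1.61-fold higher (adjusted p = 0.104). Il7r, the IL-7 receptor gene and a reported target of Gfi1, was 1.79-fold higher in CD4 and 1.19-fold in CD8 cells (adjusted p = 0.308).

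Cell cycle genes were lower together in the arrays labelled knockout. The median was -2.92 in CD4 and -1.34 in CD8 cells, with 0 of 10000 random lists as low in either. Of 29 members 22 were at least 1.5-fold lower in both subsets. Birc5 was 26.2-fold lower in CD4 and 2.88-fold in CD8 cells (adjusted p = 0.124) and Rrm2, a subunit of ribonucleotide reductase, 22.1-fold and 3.36-fold (adjusted p = 0.095). Of the members, the checkpoint kinase gene Bub1b, fell by limma over all genes (adjusted p = 0.0486), and 27 were called adjusted over the list alone.

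Further lists were low in both subsets, with sizes that differed. Helper T cell lineage genes had medians of -2.58 in CD4 and -0.63 in CD8 cells, and Tbx21, the T-bet gene, was at least 28.6-fold lower in CD4 and 4.16-fold lower in CD8 cells (adjusted p = 0.0825). CD8 T cell genes had medians of -1.52 and -0.60, with 4 of 12 members at least 1.5-fold lower in both. Their CD4 median was -0.75 after quantile normalization and -0.73 with median centring, still in the lower outer 2.5% of random lists. Over all genes limma called 1 helper lineage gene (Ifng), 2 CD8 T cell genes (Klrk1 and Eomes), 2 chemokine receptor and adhesion genes (Cxcr5 and Itgb1) and 0 glycolysis genes. Adjusted over the list alone these counts were 5, 4, 6 and 4. Ifng, Tbx21, Klrk1, Eomes and Itgb1 are also members of the memory and effector list, so these lists are not separate results. The CD8 median of the helper lineage list left the outer 2.5% without a floor (-0.40) and with the pseudocount (-0.30), the CD8 median of the chemokine receptor list with a lower floor (-0.11), averaged probe sets (-0.07) or no multi-transcript probe sets (-0.07), and the CD4 median of the glycolysis list with a higher floor (-0.14) or averaged probe sets (-0.06). Chemokine receptor and adhesion genes had medians of -0.99 and -0.11; the CD8 median turned to 0.10 with median centring, which raises all folds of a subset alike above the floor, and stayed in the lower outer 2.5% (135 of 10000 random lists as low, against 146 as deposited). Itgb1, an integrin chain gene that fell by limma (adjusted p = 0.0294), is in the list beside Ccr7, which was higher. Glycolysis genes had small medians of -0.23 and -0.18, which turned to 0.09 and 0.04 with median centring and stayed in the lower outer 2.5% (78 and 22 of 10000 random lists as low, against 86 and 24 as deposited).

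**Figure D3:**
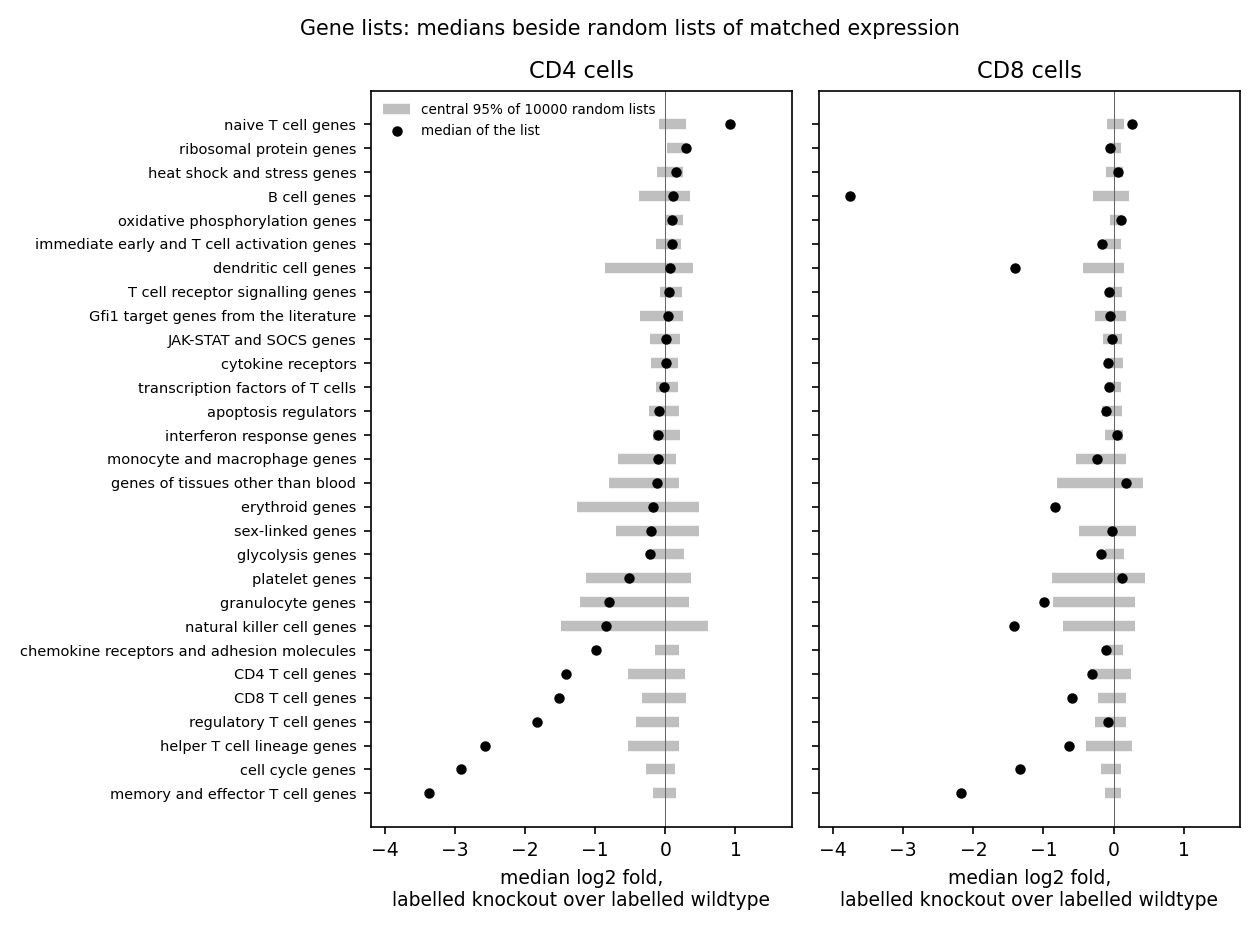
Median log2 fold (array labelled knockout over array labelled wildtype) of each of 29 gene lists, with CD4 cells on the left and CD8 cells on the right, as black points; grey bars span all but the outer 2.5% on each side of 10000 random lists of matched expression, and no bar is drawn for 2 erythroid genes in CD8 cells. Memory and effector genes lie at -3.37 and -2.18 and naive genes at 0.92 and 0.26; with median centring the CD8 medians of the glycolysis, chemokine receptor and immediate early lists and the CD4 median of the glycolysis list change sign but stay in the lower outer 2.5% of random lists.

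As deposited, other lists were in the outer 2.5% of random lists in 1 subset, and the difference between the subsets was not tested. Regulatory T cell genes were low in CD4 cells (median -1.84, 0 of 10000 random lists as low), with a median of -0.08 in CD8 cells. In CD4 cells the checkpoint receptor gene Ctla4 was 7.67-fold and the lineage factor gene Foxp3 3.72-fold lower in the array labelled knockout. CD4 T cell genes had medians of -1.42 and -0.30, with Icos 3.83-fold lower in CD4 cells. Foxp3, Ctla4, Tnfrsf4 and Izumo1r are members of both the regulatory and the CD4 T cell list. The B cell list, 4 of whose 8 members above the floor are the MHC class II genes, had a median of 0.11 in CD4 and -3.77 in CD8 cells. Natural killer cell genes had medians of -0.85 and -1.42, dendritic cell genes 0.07 and -1.41, and granulocyte genes, with 4 members, -0.80 and -0.99. All of these were, as deposited, in the outer 2.5% of random lists in CD8 cells alone. The CD8 median of natural killer cell genes was -2.25 after quantile normalization. Immediate early and activation genes had medians of 0.09 and -0.17; the CD8 value lay in that outer range (30 of 10000 random lists as low) and turned to 0.04 with median centring, still in it (49 as low). Ribosomal protein genes had medians of 0.29 in CD4 cells, in the outer range, and -0.04 in CD8 cells. Ribosomal genes left the outer range after quantile normalization (0.03), with averaged probe sets (0.27) and without multi-transcript probe sets (0.32), and CD4 T cell genes left it in CD4 cells without the last (-0.43). Granulocyte genes left it in CD8 cells under 4 settings, with medians from -0.21 to -0.67. The B cell list entered it in CD4 cells, where its median turned to -0.50 with a lower floor and -1.70 without multi-transcript probe sets. Other lists also entered it in the other subset. Dendritic cell genes did so in CD4 cells, on the higher side, under 3 settings (medians from 0.40 to 0.50). Without multi-transcript probe sets granulocyte genes did so in CD4 cells (-1.62) and regulatory T cell genes in CD8 cells (-0.48). CD4 T cell genes did so in CD8 cells without such probe sets (-0.42) or with averaged probe sets (-0.34). Of these lists limma called Klrg1 among the regulatory T cell genes and Cd22 among the B cell genes. Adjusted over the list alone it called 2 regulatory T cell genes, 2 immediate early genes, 3 natural killer cell genes, 1 gene each of the B cell, dendritic cell and granulocyte lists, and 0 of the CD4 T cell and ribosomal lists.

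Reported target genes of Gfi1 showed no joint difference. Their medians were 0.03 in CD4 and -0.05 in CD8 cells, within the range of random lists, although the CD8 median was 0.25 and outside that range with a higher floor, and 0 of 11 members above the floor differed by 1.5-fold in the same direction in both subsets. Id2, an inhibitor of DNA binding, was 5.43-fold lower in CD4 and 1.42-fold lower in CD8 cells in the array labelled knockout (adjusted p = 0.199; mean log2 fold -1.47, and -0.35 without multi-transcript probe sets), and Ets2 was 2.14-fold and 1.30-fold higher (adjusted p = 0.225). Medians within the range of random lists in both subsets were also found for interferon response genes (-0.10 and 0.05), apoptosis regulators (-0.10 and -0.11), cytokine receptors (0.00 and -0.07), JAK-STAT and SOCS genes (0.01 and -0.03), T cell receptor signalling genes (0.05 and -0.07), transcription factors of T cells (-0.02 and -0.07), heat shock and stress genes (0.16 and 0.07) and oxidative phosphorylation genes (0.10 and 0.11). The same held for monocyte and macrophage genes (-0.11 and -0.24), platelet genes (-0.51 and 0.13), sex-linked genes (-0.20 and -0.02) and genes of tissues other than blood (-0.12 and 0.18). Erythroid genes had a median of -0.18 in CD4 cells, within that range, and of -0.84 over 2 members in CD8 cells, too few for random lists. Some of these lists entered the outer range under other settings. In CD8 cells these were T cell receptor signalling genes under 6 settings (medians from -0.10 to -0.12), monocyte and macrophage genes under 3 (-0.33 to -0.97), transcription factors under 2 (-0.09 and -0.10), genes of other tissues under 2 (0.36 and 0.59), and interferon response (0.13) and heat shock genes (0.18) under 1 each. In CD4 cells they were erythroid genes (-1.004) and transcription factors (-0.15) under 1 setting each. Within these lists Fasl, the Fas ligand gene (adjusted p = 0.0294), Il2rb and Myb fell and Socs3 rose by limma over all genes. Fasl and Il2rb are also members of the memory and effector list. Adjusted over the list alone limma called 9 transcription factors, 8 cytokine receptors, 6 T cell receptor signalling genes, 5 interferon response genes, 2 apoptosis regulators, 2 monocyte and macrophage genes, and 1 gene each of the JAK-STAT and erythroid lists. It called 0 of the Gfi1 target, heat shock, oxidative phosphorylation, platelet, sex-linked and other tissue lists.

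CD8 and CD4 cells were separated by the genes that define them. Cd8a rose in CD8 cells to at least 170-fold the CD4 value among the arrays labelled wildtype and at least 177-fold among those labelled knockout (adjusted p = 6.54e-05), and Cd8b1 84.0-fold and 26.5-fold (adjusted p = 0.0047). Cd4 fell in CD8 cells by at least 62.8-fold and 58.3-fold (adjusted p = 0.00081). Of 12 CD8 T cell genes limma called 5, Cd8a, Cd8b1, Eomes, Crtam and Klrd1, and of 9 CD4 T cell genes Cd4 and Izumo1r. Among the genes that rose in CD8 cells were Eomes (7.90-fold and 9.34-fold), Crtam (9.41-fold and 7.46-fold), the killer lectin receptor gene Klrd1 (4.55-fold and 4.32-fold) and the cathepsin gene Ctsw (log2 1.82 and 1.91). The tetraspanin genes Tspan32 (4.17-fold and 4.04-fold) and Cd9 (2.94-fold and 3.07-fold) and the folate receptor family gene Izumo1r (12.9-fold and 4.73-fold) fell in CD8 cells. Klrk1 (adjusted p = 0.985), Runx3 (0.953), Nkg7 (0.208) and Gzmm (0.33) of the CD8 list did not pass the test. Zbtb7b, the ThPOK factor of the CD4 lineage, was 3.96-fold and 6.35-fold lower without passing the test (adjusted p = 0.0845). Limma called 21 genes, 15 that rose and 6 that fell in CD8 cells; without the trend it called 2 (728 at an unadjusted p under 0.05, against 822), with averaged probe sets 0 (615), after quantile normalization 9, with median centring 10, with a higher floor 20 and without multi-transcript probe sets 24. It called 241 with a lower floor, 160 with none, 141 with the pseudocount and 106 among genes above the floor on all 4 arrays. At least 2-fold differences numbered 267 higher and 429 lower in CD8 cells among the arrays labelled wildtype, and 167 and 109 among those labelled knockout.

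The difference between labelled genotypes was at least 2-fold higher in CD8 than in CD4 cells for 525 genes and at least 2-fold lower for 291. Among genes above the floor on all 4 arrays, Ccr9 had the largest difference of those higher in CD8: it was lower in CD4 cells (log2 -1.50) and higher in CD8 cells (3.37). Nkg7, a cytotoxic granule gene, was 25.1-fold lower in CD4 and had a log2 fold of -0.49 in CD8 cells, where it read 10407 in the array labelled knockout. Cxcr3 was 75.5-fold lower in CD4 and 4.45-fold lower in CD8 cells, and Itgae had log2 folds of -1.27 and 2.45. Anp32a had log2 folds of -2.13 and 1.63 with its brightest probe set, while its other probe sets gave -0.12 and 0.20, and -0.03 and 0.22. Cxcr6, at the floor on the array labelled knockout CD4, had a difference of at least 6.91. At the other end among genes above the floor stood the 4 MHC class II genes, with H2-Eb1 at 0.50 and -5.55, and G0s2, a lipase inhibitor gene, at 0.70 and -2.47. No degree of freedom is left for a test of this difference, and none was made.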

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

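The gene lists, their random lists and quantile normalization were fixed before the data were examined; the tests of explanations, with their criteria, were chosen only after the result was seen.

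The number of genes at least 2-fold apart in opposite directions followed the floor, from 2 at the 60th percentile to 615 without a floor. With the floor used here there were 9. In these the array labelled knockout lay at least 2-fold above the array labelled wildtype in 1 subset and at least 2-fold below it in the other. This difference between the subsets was not tested. As the log2 fold in CD8 minus that in CD4 cells, it was 4.87 for Ccr9, 3.75 for Anp32a, 3.72 for Itgae, 3.67 for Egln3, 3.18 for Casp1, 3.17 for Casp4, 2.97 for Tmem144 and 2.36 for Gpr155. For Plbd1, higher in CD4 and lower in CD8 cells, it was -6.31. Plbd1 read 3572.5 on the array labelled wildtype CD8, 215 on knockout CD4, 103 on wildtype CD4 and no more than the floor on knockout CD8. Tmem144 and Plbd1 have an array at the floor, so their values are bounds. Other probe sets of Anp32a gave log2 folds of -0.12 and 0.20, and of -0.03 and 0.22, in CD4 and CD8 cells. Another of Egln3 gave -0.86 and 0.81, so all of these were less than 2-fold. The other probe set of Tmem144 had a mean signal below the floor, so its folds are not given. The other probe sets of Ccr9 (-1.15 and 2.68, and -1.62 and 2.99) were at least 2-fold both ways. Among the 2246 probe sets not paired with a single gene symbol, which no comparison used, 3 were at least 2-fold higher in the arrays labelled knockout in both subsets, 31 were lower in both and 1 differed in opposite directions.

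Memory and effector genes were lower in both arrays labelled knockout. Against scaling between the arrays, the median log2 fold of the list after quantile normalization was -2.18 or lower in both subsets. For a labelling or hybridization batch that acts on probe sets without regard to function, 0 of 10000 random lists had a median as low. The same random lists had singled out this pattern, so they cannot decide on a batch. Of the control transcripts, lys differed between the labelled genotypes by a log2 value of -0.74 in CD4 and -0.69 in CD8 cells, and phe by 0.04 and 0.01. A candidate explanation is cells with high CD44 in the arrays labelled wildtype: Cd44 itself had a log2 fold of -4.51 or lower in both subsets and the naive list was high in both, although all 4 samples are labelled CD44 low. The sample titles end in N for the knockout and M for the wildtype label, letters that the labels do not explain. Loss of Gfi1 stays open and cannot be told apart from a difference in CD44 sorting, because 0 arrays labelled wildtype have Cd44 as low as the arrays labelled knockout.

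Gfi1 signal was not lower in the arrays labelled knockout. Background signal of the probe set is argued against by a signal at least 26.1 times the floor on both of these arrays. A transcript of the disrupted allele that the probe set still detects and a wrong genotype label may each account for it and cannot be told apart, because only 1 probe set of Gfi1 is named and its place relative to the deleted part is not given. No biological explanation was tested.

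MHC class II genes were higher in the array labelled wildtype CD8 than on the other 3 arrays. B cells as the source of this signal stay open. Of 11 B cell genes outside MHC class II, 1 was at least 2-fold above each other array. Only 4 of the 11 lay above the floor on an array, and the others could not count. The criterion was set on all 11 genes, and 1 of 11 (9.09%) was a share low enough to exclude B cells under it. That outcome rests largely on the genes that could not count, while 1 of the 4 that could stood out. It is therefore not taken here as an exclusion. Where Cd74 read 16735, Cd79b read 759, against 738 on the array labelled knockout CD8. Cd79a (69.2) and Ms4a1 (79.7) were highest on the array labelled wildtype CD8 but stayed below the floor. Dendritic cells in the sample stay open as well: 4 of 9 genes of their list were at least 2-fold above each other array, between the shares set to exclude and to accept them. As a description added after that result, 0 of 10000 random lists held as many, while Cd83, Bst2 and Zbtb46 of the list did not stand out in this way, and Bst2 is also in the interferon list. The sort on CD8 and CD44 would remove cells without CD8, B cells among them, although some dendritic cells of the spleen carry CD8 alpha, and a biological difference between the labelled genotypes was not tested for these genes.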

How the results depend on the processing

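All alternatives were chosen before the data were examined, except the restriction to genes above the floor on all 4 arrays, which was chosen after seeing them. No paired analysis was possible because the labels give no replicate numbers and each group has 1 array. Arrays have no read depth; signal over background sets the limit, and the counts of genes at least 2-fold apart follow the floor. The number of lists in the outer range of random lists in both subsets stayed within 1.5 times its value under each alternative run for it. Of the other list medians 397 kept their place inside or outside the outer range. A further 24 entered and 15 left it, 3 entered it on the other side, and 4 in that range reversed. Sizes could change without a change of place. After quantile normalization, CD8 T cell genes in CD4 cells went from -1.52 to -0.75 and natural killer cell genes in CD8 cells from -1.42 to -2.25. Of the mean log2 folds of named genes 1095 stayed within the spread used and 220 moved. The sign changed for 13 of these values, from 7 genes, and for 58 list medians, most of them within the random range under both settings; 0 of these were at least 2-fold as deposited. For Anp32a the mean log2 fold between labelled genotypes went from -0.25 to 0.01 with median centring and 0.09 without multi-transcript probe sets. Where no cause follows from the alternative itself, the cause was not tested. Genes of opposite direction, 9 as deposited, numbered 67 with the floor at the 25th percentile, 2 at the 60th, 615 without a floor and 198 with log2 of the value plus 16. For the counts in the paragraphs below, the settings not named for a count left it within 1.5 times.

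Quantile normalization gave 266 genes at least 2-fold higher in the array labelled knockout in CD4 cells and 49 in both subsets, and limma called 4 genes for genotype and 9 for subset. Centring on medians gave 421 higher genes in CD4, 173 in CD8 and 65 in both, with 17 and 10 limma calls and a Gfi1 log2 fold of 0.66 in CD4 cells. It raised the median fold of genes above the floor on all 4 arrays to 0.33 in CD4 and 0.21 in CD8 cells. With that shift it reversed the sign of the medians of the immediate early list in CD8 cells (0.044), the chemokine receptor and adhesion list in CD8 cells (0.10) and the glycolysis list in CD4 (0.089) and CD8 cells (0.038), while all of these stayed in the lower outer 2.5% of random lists, which shift alike.

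The floor changed the counts by construction, since it sets which low signals can differ. At the 25th percentile, 396 genes were higher and 1116 lower in CD4 cells, 314 and 808 in CD8 cells, and 50 and 312 in both; the effect was at least 2-fold higher in CD8 for 1060 genes and lower for 797. Mean effects of at least 2-fold numbered 866 for genotype and 629 for subset, and limma called 505 and 241. At the 60th percentile, these counts were 78 and 250 in CD4, 33 and 100 in CD8, 11 and 54 in both, 182 and 109 for the difference between subsets, 165 and 103 for mean effects, and 31 limma calls for genotype. Without a floor, they were 1170 and 2164 in CD4, 1049 and 1916 in CD8, 225 and 779 in both, 2109 and 1887 for the difference, 2612 and 2419 for mean effects, and 327 and 160 limma calls. With log2 of the value plus 16, they were 690 and 1564 in CD4, 597 and 1233 in CD8, 98 and 441 in both, 1532 and 1273 for the difference, 1278 and 1023 for mean effects, and 284 and 141 limma calls.

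With the mean of all probe sets of a gene limma called 0 genes for genotype (747 at an unadjusted p under 0.05) and 0 for subset (615). Without probe sets that may detect several transcripts it called 47 for genotype, of which 30 were among the 47 called as deposited. Without the trend it called 0 for genotype (990) and 2 for subset (728). Genes above the floor on all 4 arrays, fewer by construction, gave 350 lower in CD4, 161 lower in CD8 and 86 lower in both, 294 and 175 for the difference, 260 and 174 for mean effects, and 201 and 106 limma calls. With a threshold of 1.5-fold, 627 genes were higher and 1256 lower in CD4, 356 and 792 in CD8, 116 and 405 in both, and 1191 and 849 for the difference. With 3-fold, the counts were 46 and 329, 29 and 147, 11 and 67, and 193 and 94. Leaving out each array in turn left 1 pair of arrays and no test: mean genotype effects of at least 2-fold ranged from 441 without either CD4 array to 795 without either CD8 array, and mean subset effects from 276 without either array labelled wildtype to 696 without either array labelled knockout.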

Other observations

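The test on genes next to Gfi1 was set before its result was seen, and the genes of other blood cells were singled out after their values were seen.

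Single genes expressed in myeloid cells read higher on the array labelled wildtype CD8, while the monocyte and macrophage list fixed beforehand had a CD8 median of -0.24, within the range of random lists. Mpeg1, the perforin-2 gene of macrophages and dendritic cells, read 4610 there, 294 on the array labelled wildtype CD4, and less than the floor on both arrays labelled knockout. Irf8, a transcription factor gene of dendritic cells, macrophages and B cells, read 2672 there, 912 on wildtype CD4, 298 on knockout CD4 and 309 on knockout CD8. Tyrobp, a signalling adaptor gene of myeloid and natural killer cells, read 883 there and 239 on wildtype CD4, and Plek read 3196 and 319, but Fcer1g of the same list read 251 and 248. The immunoglobulin gene Ighm read between 10871 and 16664 on all 4 arrays, and Cd79b read 759 on wildtype CD8 and 738 on knockout CD8.

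Sex-linked genes were read on every array. Xist, expressed from the inactive X chromosome, ranged from 3430 to 5236, and the Y-linked gene Eif2s3y from 1155 to 1302. The Y-linked genes Kdm5d and Uty were above the floor on all 4 arrays as well, from 316 to 508 and from 152 to 274. Of the control transcripts, lys differed between the labelled genotypes by a log2 value of -0.74 in CD4 and -0.69 in CD8 cells, and phe by 0.04 and 0.01.

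A hypothesis was that flanking DNA of another mouse strain, carried beside the disrupted gene, might give differences in genes next to Gfi1 on its chromosome. Of 40 genes above the floor on at least 1 array, 20 on each side of Gfi1, 3 were at least 2-fold apart in the same direction in both subsets: Tgfbr3 was higher in the arrays labelled knockout (log2 1.26 in CD4 and 1.16 in CD8), and Pxmp2 (-1.37 in both) and Pole (-2.53 and -1.38) were lower. The median of 10000 random sets of as many genes was 1, and 700 sets held at least 3, so the count lay above the median and short of the outer 2.5%, and the test did not decide.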
